A study of Mus musculus with 4 samples.

How the data were processed

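Gene expression was measured by 10x Genomics droplet sequencing in 4 libraries of sorted mouse heart cells: Hic1 CreERT2 tdTomato+ cells of undamaged hearts, the same cells 7 days after LAD ligation, Hic1-citrine+ cells of undamaged hearts, and PDGFRa H2BGFP+ cells of undamaged and ligated hearts. Per the labels, each tdTomato library pooled 3 hearts, the citrine library 3 hashed hearts and the PDGFRa library 4 hashed hearts. The deposited files hold UMI counts per gene and cell barcode, made by the authors with Cell Ranger on a modified mm10 reference. Seurat 2.1 is also named in the labels, but the deposited counts are whole numbers with totals that differ between cells, so they are not normalised. Per the file headers, Cell Ranger 3.0.2 wrote the citrine and PDGFRa counts; the headers of the tdTomato counts give no version. The labels give the Chromium 3' kit v2 for every library, yet the barcode sets of the 2 pairs of libraries differ. Barcodes of the undamaged and ligated tdTomato libraries began with 477 and 480 different runs of 6 bases and those of the citrine and PDGFRa libraries with 960 each. The last 2 shared all of theirs, while 28.1% of the undamaged tdTomato barcodes began with a run found in the citrine library. Sequencing was on a NextSeq 500, per the labels. All 4 files share 28001 features, of which 3 are reporter sequences, and the hashed libraries add 4 hashtags.

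Cells with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs were kept. Each library was clustered on its own from counts scaled to 10000 UMIs and log-transformed, with 2000 variable genes, 30 principal components, 20 neighbours and Leiden resolution 1 (scanpy 1.11.5, leidenalg 0.10.2, python-igraph 0.11.9, scikit-learn 1.9.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3; figures with matplotlib 3.10.9). The 273 genes of the 20 gene lists that are no cell type marker were left out of the clustering, as were mitochondrial, ribosomal, reporter, Xist and Y-linked genes. A cluster took the class with the largest share of its markers detected, out of 11 cell type lists (fibroblast, pericyte, smooth muscle, endothelial, macrophage and monocyte, lymphocyte, neutrophil, cardiomyocyte, Schwann, epicardial, erythroid). Detection also required a minimum level relative to the mean CPM over all clusters. Where that class was pericyte or smooth muscle, the cluster took whichever of these lists had the higher mean log2 CPM ratio to the mean over clusters. At least 3 markers, each in at least 25% of its cells, were needed, and the 10 leading genes were not to hold more markers of another class. A cluster with a median UMI count under 1/3 of that of its library and none of its class markers among the leading genes was left unnamed. Leading genes were those with the highest CPM ratio to clusters of the other classes, in at least 10% of the cluster's cells. Clusters of the other classes were pooled over the 4 libraries, so PDGFRa clusters were set against cells of the tdTomato and citrine libraries only. Clusters with 6 of 8 cycling markers over 2-fold higher than in the rest of the library were called cycling, and each of their cells was given the class with the largest share of its markers seen. Fibroblast-like clusters took the name of 1 of 4 subset lists (Sca1-high, Wif1, activated, interferon) when at least 60% of its markers were over 2-fold higher than in the rest of the library. Class names end in "-like" since they rest on RNA alone. Cells with over 1 hashtag were kept in the library totals.

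For comparisons between libraries, UMIs were summed over fibroblast-like cells and expressed as CPM, scaled to the UMI total of the class, with a pseudocount of 1 UMI. Genes with at least 20 UMIs in the 2 sums entered. Ratios carry exact 95% intervals for Poisson counts, shares of cells exact Clopper-Pearson 95% intervals, and a fold against a count of 0 is taken against a floor of 3 counts over the library; intervals and limits cover counting error only. A list was described by its median log2 ratio and by the percentile of that median among 10000 random lists of the same size matched over 20 expression bins. Below 2.5 or above 97.5 it was described as standing apart. No test was made between single libraries. Of the 298 genes of the lists, 297 have a feature in the files. The lists were fibrillar collagens and elastic matrix, basement membrane, collagen crosslinking and processing, myofibroblast and activation, matrifibrocyte and cartilage matrix, osteogenic, adipogenic, Sca1-high progenitor, resting cardiac fibroblast, chemokines and cytokines, complement, interferon response, cell cycle, Wnt modulators and targets, TGF-beta and BMP signalling, proteases and inhibitors, growth factors and receptors, dissociation and immediate early, glycolysis, and ER folding and secretion. Shares of cells with a UMI of Hic1, Pdgfra or Mki67 were taken after thinning every cell to 2000 UMIs. At first a single random draw was used; after the values had been seen it was replaced by the mean number of cells over all draws, rounded to whole cells. Coordinates are from GENCODE M21.

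A cell was assigned to a heart when exactly 1 hashtag lay above the 99th percentile of the lower of 2 Gaussian components of its log10 count. This assigned 62.7% of the citrine cells (6793) and 85.3% of the PDGFRa cells (10715); 30.4% and 6.00% had none, and 6.95% and 8.74% had over 1. For the citrine hearts, counts were summed per heart for Sca1-high-like and for other fibroblast-like cells and tested with edgeR 4.0.16 (quasi-likelihood, TMM, filterByExpr, heart as a block; limma 3.58.1, R 4.3.3). The fit covered 11889 genes, and Benjamini-Hochberg adjustment at 0.05 was over the 238 tested genes that had been held out of the clustering and do not name the Sca1-high subset. The sums of the same heart deviated together, with correlations across genes of 0.200, 0.206 and 0.180, which is why the heart was a block. A test of pericyte-like against fibroblast-like cells required 30 cells of each in every heart and was not made. A test of ligated against undamaged PDGFRa hearts required hashtags tied to a condition, which the labels do not give, and was not made either.

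The sample groups, lists, filters, tests, the alternatives named as planned and the rule for named genes were fixed before the data were examined. By that rule the text names 14 fixed genes and the reporters. It adds the 12 highest and 12 lowest log2 ratios among genes with at least 50 CPM in 1 of the libraries and intervals that do not overlap, and up to 4 members of each list with the largest ratio. Mitochondrial, ribosomal protein, haemoglobin, Xist and Y-linked genes and unnamed gene models were left out. For the heart test it takes the fixed genes and up to 4 members of each list with the smallest adjusted p. Alternatives were no cell filter, at most 5% mitochondrial UMIs, libraries clustered together, Leiden resolution 0.5, doublets called by scrublet left out, scaling by the median ratio, no count filter or 100 UMIs, a pseudocount of 5, all kept cells, and totals without mitochondrial, ribosomal and dissociation genes. Shares were also taken unthinned and at 1000 UMIs. For the heart test they were DESeq2 1.42.0, no TMM, no filter, no block, leaving out each heart, and hashtags assigned at 80% of hashtag counts. Scrublet called 1 citrine and 2 PDGFRa cells, and of 753 and 1098 cells with over 1 hashtag it called 0% and 0.0911%, so it did not remove doublets there.

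The comparisons between libraries and the heart test were tried on simulated data built from these files. For the ligation comparison, with 11905 genes, the intervals lay apart for 96% of 100 genes changed by a log2 of 2, for 89% of 100 changed by 1, and for 0.581% of 11705 unchanged genes. For the citrine comparison, with 13947 genes, these were 94%, 80% and 1.30% of 13747. A glycolysis list shifted by a log2 of 1 was returned at 1.02 and 0.98, at percentile 100 both times, and 0 of 19 other lists stood apart. For the heart test, with 11751 genes, 72.2% of 97 genes changed by a log2 of 1 and 36.1% of 97 changed by 0.5 were called, along with 1 of 11557 unchanged genes. The simulated hearts shared the same mean profile, and the adjustment there was over all 11751 genes rather than the held-out ones. These percents are thus not the power of the reported heart test.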

Results

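Mesenchymal cells of the mouse heart were profiled by droplet single-cell RNA sequencing in 4 libraries. Tying off the left anterior descending coronary artery (LAD ligation) is a model of myocardial infarction. The first library held tdTomato+ cells of Hic1 CreERT2 tdTomato mice, in which cells that expressed Hic1 at the time of induction carry a lasting label, from 3 pooled undamaged hearts. The second held tdTomato+ cells from 3 pooled hearts 7 days after ligation. The third held cells positive for a Hic1-citrine reporter, which follows present Hic1 expression, from 3 undamaged hearts marked with antibody hashtags. The fourth held PDGFRa H2BGFP+ cells, a nuclear reporter of fibroblasts and their progenitors, from 4 hashed hearts, 2 undamaged and 2 ligated. The stated purpose was to describe how heterogeneous the mesenchymal progenitors of the heart are. Each group was 1 library, so no comparison between libraries could be checked against replicates, and intervals on them cover counting error only. The deposited barcodes numbered 2853, 4292, 11338 and 13830 in that order, with 9885698, 18028737, 97467582 and 122716283 UMIs in all. After filtering, 2786, 4263, 10838 and 12567 cells remained, with medians of 3453, 3668, 8038.5 and 7729 UMIs per cell.

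Fibroblast-like cells made up most of every library, and pericyte-like and smooth-muscle-like cells took larger shares of the tdTomato libraries than of the others. Fibroblast-like clusters held 86.5% (exact 95% interval 85.2 to 87.8) of the undamaged tdTomato cells and 73.6% (72.2 to 74.9) of those after ligation. They held 95.4% (95 to 95.8) of the citrine cells, and every PDGFRa cluster took this name or was a cycling cluster of fibroblast-like cells. Classes were given to whole clusters, so cells too few to form one were not counted. Pericyte-like cells, marked by Rgs5, Kcnj8 and Vtn, were 6.68% (5.78 to 7.67) of the undamaged tdTomato library and 19.1% (18.0 to 20.4) of the ligated one. In the citrine library they were 2.05% (1.79 to 2.33), and in the PDGFRa library no cluster took that name. Smooth-muscle-like cells, with the contractile genes Myh11 and Acta2, were 5.67% of the undamaged and 7.27% of the ligated tdTomato library, and no citrine cluster took that name. An endothelial-like cluster of 31 cells, with Fabp4 and Cdh5 and also the interferon genes Iigp1 and Cxcl10 among its leading genes, appeared in the undamaged tdTomato library alone. No cluster was named as macrophages, lymphocytes, neutrophils, cardiomyocytes, Schwann cells, epicardium or erythroid cells, although a fibroblast-like PDGFRa cluster of 66 cells had Wt1, an epicardial marker, among its leading genes.

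Among the fibroblast-like cells, clusters named Wif1-like or activated-like differed between libraries, but these names rest on a cut at 60% of the markers. The Wif1-like cluster held 115 undamaged tdTomato cells (4.13%, 3.42 to 4.93) and was led by Cytl1, Wif1 (a secreted Wnt inhibitor), Comp and Prg4. No cluster took that name after ligation. The activated-like cluster after ligation held 396 cells (9.29%) and had Sfrp2, Ddah1, Cthrc1, Ptn and Lox among its leading genes. In the citrine library 668 cells (6.16%) fell in a cluster given that name, led by Prg4, Ltbp2, Comp and Cilp, and in the PDGFRa library 928 cells (7.38%), led by C1qtnf3, Tnc and Cilp. No undamaged tdTomato cluster took it, although one of 285 cells, with Cilp, Postn and Ltbp2 among its leading genes, held 4 activated markers, against 6 in the citrine cluster. Sca1-high-like cells were 7.32%, 8.94%, 8.09% and 15.3% (14.7 to 16.0) of the undamaged tdTomato, ligated tdTomato, citrine and PDGFRa libraries. With the 4 libraries clustered together, these shares were 0.179%, 0.0469%, 21.9% and 13.3%, so they depended strongly on the clustering. Interferon-like clusters with Ifit3 and Rsad2 held 1.63% of the citrine and 1.77% of the PDGFRa cells. A cluster of 273 citrine cells with a median of 2355 UMIs was left unnamed, since that was under 1/3 of the median of its library. A PDGFRa cluster of 320 cells (median 2673 UMIs), which also had Lars2 and Gm42418 among its leading genes, lay above that line and counted as fibroblast-like. Cycling clusters held 22 cells of the ligated tdTomato, 36 of the citrine and 28 of the PDGFRa library, and after ligation 13 of the 22 were fibroblast-like and 7 pericyte-like.

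**Figure D1:**
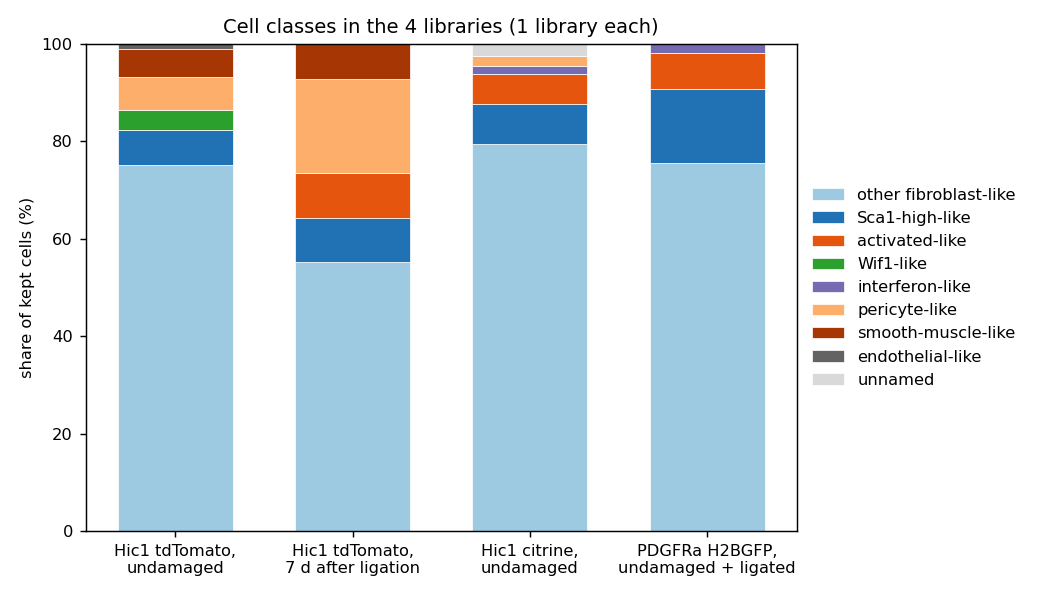
Share of kept cells (%, vertical axis from 0) in each class or fibroblast subset, stacked for the 4 libraries, with 1 library per bar. The pericyte-like part reaches 19.1% in the ligated tdTomato library, and the Wif1-like part (4.13%) appears in the undamaged tdTomato library.

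A Hic1 transcript was found far more often in citrine cells than under the tdTomato label. With fibroblast-like cells thinned to 2000 UMIs each, 43.9% (42.9 to 44.9) of 10264 citrine cells held a Hic1 UMI. The shares were 4.15% (3.35 to 5.07) of 2195 undamaged tdTomato cells, 6.70% (5.83 to 7.65) of 3001 after ligation, and 6.45% (6.03 to 6.90) of 12431 PDGFRa cells. Hic1 encodes a transcriptional repressor and lies on chromosome 11 from 75164565 to 75169519 (mm10, minus strand, ENSMUSG00000043099). Pdgfra, a receptor tyrosine kinase on chromosome 5 from 75152292 to 75198215 (ENSMUSG00000029231), was found in 40.9%, 34.4%, 49.2% and 25.7% of the undamaged tdTomato, ligated tdTomato, citrine and PDGFRa cells. Mki67, a proliferation marker, was found in 0.137%, 0.20%, 0.156% and 0.209%. Pericyte-like cells held a Hic1 UMI in 17.2% (5.85 to 35.8) of 29 undamaged tdTomato, 10.8% (8.28 to 13.8) of 528 ligated tdTomato and 57.5% (49.9 to 64.9) of 179 citrine cells. As background, 1 of 31 endothelial-like cells of the undamaged tdTomato library held a Hic1 UMI before thinning (3.23%, 0.0816 to 16.7), and after it 17.4% of 23 held a Pdgfra UMI. In smooth-muscle-like cells of that library (median 2626 UMIs) the Hic1 and Pdgfra shares were both 0.833% (0.0211 to 4.56; 1 of 120 cells), and after ligation 3.80% (1.75 to 7.09) of 237 smooth-muscle-like cells held a Hic1 UMI. In CPM, Hic1 in smooth-muscle-like cells stood at 2.54 (0.0642 to 14.1) in the undamaged and 13.9 (7.59 to 23.3) in the ligated tdTomato library, against 20.7 (17.9 to 23.9) and 32.2 (29.3 to 35.2) in fibroblast-like cells. Fibroblast-like cells under 2000 UMIs, 216, 136, 79 and 136 in the same order of libraries, did not enter. Of the pericyte-like cells, 157 undamaged tdTomato, 288 ligated tdTomato and 43 citrine cells did not enter, so the undamaged share rests on few, deep cells. Thinned to 1000 UMIs, which left none out, Hic1 shares of pericyte-like cells were 5.91% (2.99 to 10.3) of 186, 6.37% (4.80 to 8.27) of 816 and 42.8% (36.2 to 49.6) of 222.

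At 7 days after ligation, fibroblast-like tdTomato cells carried far more RNA of activation genes and more of fibrillar matrix genes than those of undamaged hearts, and far less of the Wnt inhibitor gene Wif1. Cthrc1, a secreted protein of remodelling matrix, was 109-fold higher (77.8 to 157), at 410 against 3.77 CPM (UMIs of the gene scaled to the total of the class). Postn, the matricellular protein periostin (chromosome 3, 54361109 to 54391037, ENSMUSG00000027750), was 5.85-fold higher (5.57 to 6.14), at 1152 against 197 CPM. Tnc, tenascin C, was 16.9-fold higher (11.7 to 25.4), Fn1, fibronectin, 6.91-fold (6.40 to 7.47), and Lox, which crosslinks collagen, 5.97-fold (5.13 to 6.98). Wif1 (chromosome 10, 121033960 to 121100650, ENSMUSG00000020218) had 425 UMIs in undamaged and 0 in ligated hearts, at least 228-fold lower against a floor of 3 UMIs (exact interval from 185). The question was how cells of the Hic1 lineage differ after injury. Counts were summed over 2411 undamaged cells (9018137 UMIs) and 3137 cells after ligation (14537230 UMIs), and the median log2 ratio over 12194 genes was -0.06.

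The genes with the highest ratios also included Ddah1, an enzyme that degrades an inhibitor of nitric oxide synthase (19.2-fold, 14.7 to 25.4), the neutrophil chemokine Cxcl2 (13.2-fold, 10.6 to 16.7), and Thbs4, a thrombospondin (6.81-fold). Fam101b, the histone variant H2afj, the small heat shock protein Hspb1 and Ptn were 5.56-, 5.31-, 5.0- and 4.38-fold higher. Of the named genes with at least 50 CPM in 1 of the libraries, the lowest was Cytl1, a secreted cytokine-like protein, at 19.0-fold lower. Angptl7 and Prg4, the joint lubricant lubricin, were 5.66- and 4.6-fold lower. AY036118 was 4.51-fold lower, Ddit4, an inhibitor of mTOR signalling, 4.17-fold, and Id1, a target of BMP signals, 3.98-fold. Vit, Adm, Anxa11, Gsn, Bmp4 and Igfbp3 were between 2.64- and 3.31-fold lower. Of the genes fixed in advance, Runx1, a transcription factor, was 4.27-fold higher (3.32 to 5.57), Acta2, smooth muscle actin, 2.67-fold (2.39 to 2.98), and Col1a1, the main fibrillar collagen chain, 2.1-fold (2.05 to 2.15). Runx2 stood at 1.84 times the undamaged level, Hic1 at 1.55 times (1.31 to 1.85), tdTomato at 1.44 times and Ly6a, which encodes Sca1, at 1.12 times. The fibroblast genes Pdgfra, Tcf21 and Pi16 stood at 0.719 (0.681 to 0.758), 0.670 and 0.619 times. Mki67 (1.48, 0.752 to 3.08) and Pparg (0.806, 0.327 to 2.05) had intervals that held 1, so no difference was detectable at this depth. Rgs5, a pericyte marker, was 2.09 times as high, in a library that held more pericyte-like cells.

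The myofibroblast and activation list stood highest against random lists of like expression. Its median log2 ratio was 1.42 (percentile 100 of 10000 lists), with 11 of 16 measured members over 2-fold higher, 0 over 2-fold lower and 5 between. Fibrillar collagens and elastic matrix had a median of 0.64 (percentile 100), with 2 of 14 members over 2-fold higher and 12 between; Col5a2 and Col3a1 were 1.97 and 1.90 times as high. Collagen crosslinking and processing had a median of 0.21 (percentile 98.9), with 2 of 14 over 2-fold higher, among them P4ha3 at 15.4-fold (5.81 to 57.5); over all kept cells the median was 0.18, inside the random lists. The matrifibrocyte and cartilage matrix list split, with 5 of 13 members over 2-fold higher, 3 over 2-fold lower and a median of 0.24 (percentile 99.2); with genes of at least 100 UMIs or with no filter on counts it was 0.12, and over all kept cells 0.070, inside the random lists each time. Sfrp2 was 3.98-fold higher, Chad had 0 UMIs after ligation and was at least 18.3-fold lower (exact interval from 14.1), and Acan was at least 5.17-fold higher (from 3.90). Basement membrane genes had a median of -0.18 (percentile 8.02) with all 12 members between, such as Col4a2 at 1.59 and Lamb2 at 0.717 times. The activated-like cluster of 396 cells (median 7739 UMIs) was also left out, a setting chosen after the data were seen. It had been named by activation markers and was left out of the ligated library only, while the undamaged cluster of 285 cells with 4 such markers stayed in, so lower values follow in part by construction. In that setting the myofibroblast median was 0.05 (percentile 82.5), the fibrillar median -0.13, the crosslinking median -0.01 and the matrifibrocyte median -1.46. The log2 ratios of Cthrc1, Cxcl2 and Tnc then went from 6.73 to 3.56, from 3.71 to 2.62 and from 4.04 to 1.64. Those of Postn, Fn1, Ddah1 and Runx1 went from 2.55, 2.79, 4.24 and 2.08 to 0.09, 0.30, 0.45 and 0.05, and Col1a1, from 1.07, came to -0.23. Ptn, Sfrp2, Ifi44 and Col3a1, all higher after ligation with that cluster included, came to -0.71, -0.37, -0.53 and -0.041.

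Chemokines and cytokines had a median of 0.77 (percentile 100), with 6 of 15 members over 2-fold higher and 1 lower. Cxcl9 was 6.67-fold higher (2.42 to 25.6), Cxcl10 3.08-fold and Ccl7, a monocyte chemoattractant, 2.75-fold, while Ccl19 stood at 0.354 times. Complement genes showed no common direction (median -0.08, percentile 36.0; 1 of 9 higher, 1 lower), with C4b at 2.16 and Cfb at 0.254 times. The interferon response list had a median of 0.11 (percentile 92.0), with Ifi44 3.00-fold and Rsad2 2.04-fold higher and 14 of 16 members between. Cell cycle genes had a median of 0.55 (percentile 100), with 4 of 22 members over 2-fold higher, among them Cdk1 at 4.08-fold and Ccna2 at 3.28-fold. This came from few cells: without the 13 fibroblast-like cells of the cycling cluster, a setting chosen after the data were seen, the median was -0.84, and the log2 ratios of Cdk1 and Ccna2 were 1.24 and -1.55; the undamaged library had no cycling cluster to leave out. Immediate early genes, which cell dissociation itself induces, had a median of 0.34 (percentile 99.98), with 2 of 17 over 2-fold higher, Jun at 2.75-fold and Zfp36 at 2.13-fold, and Nr4a1 at 0.564 times; over all kept cells the median was 0.16, inside the random lists. The largest fibroblast-like cluster after ligation (715 cells) had the heat shock gene Dnajb1 among its leading genes, whereas the largest undamaged clusters were led by Smoc2, Dpep1 and Clec3b (593 cells) and by Inmt and Apoe (571 cells).

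Wnt modulators and targets had the lowest median, -0.52 (percentile 0.09), with 5 of 13 members over 2-fold lower and 1, Sfrp2, over 2-fold higher; with genes of at least 100 UMIs it was -0.13 and no longer outside the random lists. Rspo3, a Wnt agonist, stood at 0.0962 times and Nkd1, a feedback inhibitor, at 0.276 times. The Sca1-high progenitor list had a median of -0.50 (percentile 0.02), with Dpp4 at 0.369, Efhd1 at 0.539 and Gfpt2 at 0.625 times and 11 of 12 members between. Glycolysis genes had a median of -0.27 (percentile 1.69) with all 13 between, such as Pfkp at 0.585 and Eno1 at 0.610 times; at most 5% mitochondrial UMIs (-0.25) or over all kept cells (-0.044) they lay inside the random lists. Adipogenic genes had a median of -0.34 (percentile 3.44), with Cebpb at 0.491 and Apoe at 0.641 times and Car3 at least 10.7-fold lower (exact interval from 7.96). Resting cardiac fibroblast genes had a median of -0.16 (percentile 6.82), with Cxcl14 3.39-fold higher and the other 16 between, such as C7 at 0.578 times. Osteogenic genes had a median of -0.02 (percentile 62.1; 1 of 9 higher, 1 lower), with Spp1 3.27-fold higher and Msx1 at 0.581 times. TGF-beta and BMP signalling had a median of -0.15 (percentile 14.3; 0 of 16 higher, 2 lower), with Smad6 at 0.404 times. Proteases and inhibitors had a median of -0.08 (percentile 29.3; 2 of 15 higher, 1 lower), with Adam12 at 4.89-fold, Timp1 at 3.31-fold and Mmp3 at 0.497 times. Growth factors and receptors had a median of 0.06 (percentile 80.6; 1 of 16 higher, 4 lower), with Vegfa at 0.436 and Igfbp5 at 0.442 times. ER folding and secretion genes had a median of 0.13 (percentile 90.6) with all 17 between, such as Xbp1 at 1.84 times.

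Summed over each list, markers of other cell types in these fibroblast-like cells were as follows, undamaged first and ligated second. Pericyte markers took 422 and 569 CPM, smooth muscle markers 272 and 505 CPM, and endothelial markers 114 and 125 CPM. Neutrophil-list genes took 771 and 913 CPM, macrophage and monocyte markers 10.6 and 10.1 CPM, and cardiomyocyte markers 18.4 and 30.9 CPM. The neutrophil list holds G0s2, also on the adipogenic list and among the leading genes of the largest undamaged cluster (593 cells) within its library. In smooth-muscle-like cells G0s2 alone, at 274 and 252 CPM, equalled the sum of the neutrophil list. That sum thus does not show neutrophil RNA. Schwann cell markers took 45.6 and 29.0 CPM, lymphocyte markers 0.333 and 0.550 CPM, epicardial markers 1.22 and 1.72 CPM, and erythroid markers 0.222 and 0.413 CPM. The fibroblast markers themselves took 87467 and 48974 CPM.

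**Figure D2:**
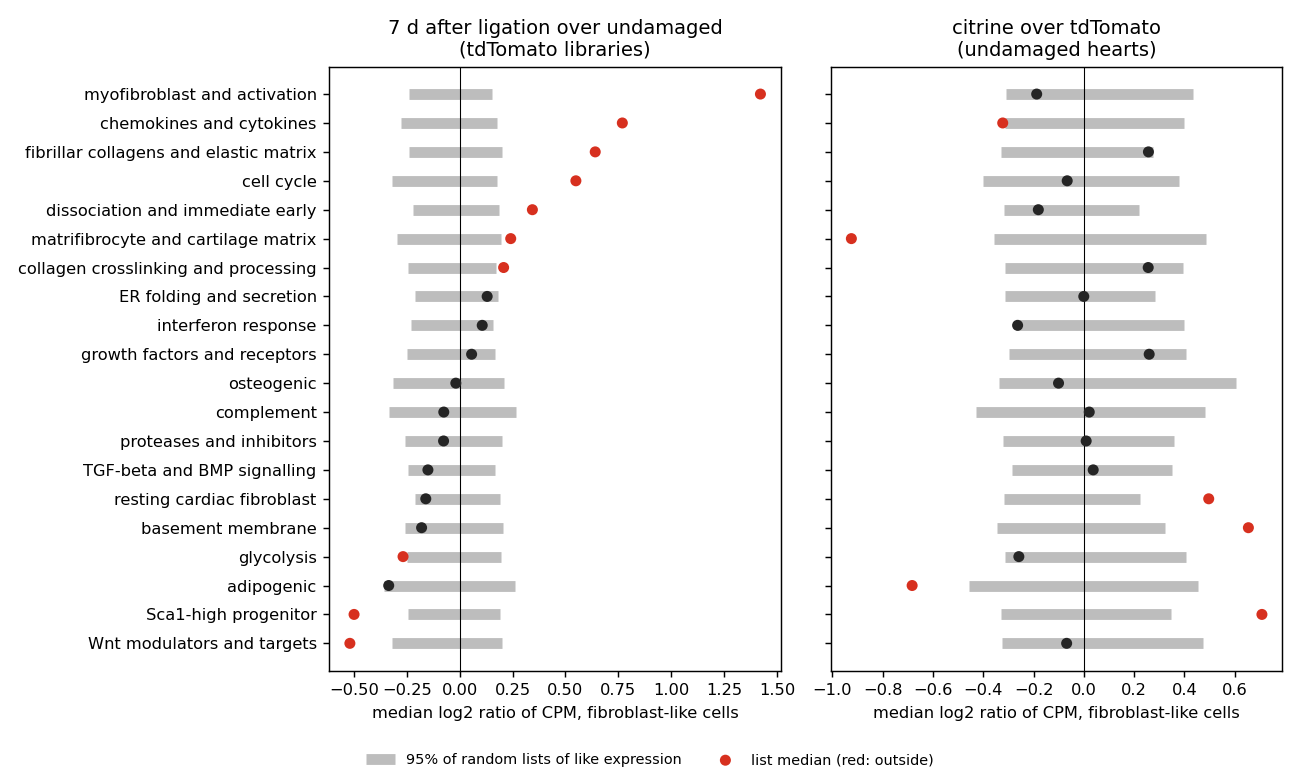
Median log2 ratio of CPM (horizontal axis) of the 20 gene lists in fibroblast-like cells, for ligated over undamaged tdTomato cells (left) and citrine over tdTomato cells of undamaged hearts (right). Dots are list medians, red where outside the central 95% of random lists of like expression (grey bars); the myofibroblast list lies at 1.42 on the left and the matrifibrocyte list at -0.92 on the right.

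Between the reporters in undamaged hearts, citrine cells carried far more Hic1 RNA, and more RNA of Sca1-high genes, than cells under the lasting tdTomato label. Hic1 was 14.5-fold higher (12.6 to 16.8), at 301 against 20.7 CPM. Ackr3, a scavenging chemokine receptor, was 6.61-fold higher, Cd248, endosialin, 2.59-fold, and Tcf21, a transcription factor of cardiac fibroblasts, 2.34-fold (2.24 to 2.45); these 3 were also 3.12-, 1.31- and 1.98-fold higher in the PDGFRa than in the ligated tdTomato library. Wif1 was 11.8-fold and Fmod, the collagen-binding proteoglycan fibromodulin, 11.2-fold lower in citrine cells. The question was how cells with present Hic1 expression compare with the inducible lineage. The sums covered 10343 citrine cells (94735559 UMIs) and 2411 tdTomato cells (9018137 UMIs), with a median log2 ratio of 0.03 over 14090 genes. The library preparations differed as well: of the ligated tdTomato barcodes 99.3% began with 6 bases also found in the undamaged tdTomato library and 26.9% with 6 bases found in the citrine library, and of 135 genes at least 4-fold higher in the citrine library, 91.1% were also at least 2-fold higher in the PDGFRa than in the ligated tdTomato library.

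That limit bears on most genes with the highest ratios. Scand1 was 206-fold higher (104 to 476), and its level in fibroblast-like cells was 177 CPM in the PDGFRa and 4.68 CPM in the ligated tdTomato library. Cebpb, a transcription factor of adipocytes and inflammation, was 43.9-fold higher (34.9 to 56.1), with 799 CPM in the PDGFRa and 3.92 CPM in the ligated tdTomato library. Zfp771, Jdp2, Ino80b, Imp3, Lars2, Med30, Erdr1, Taf10, Rab24 and Hras were between 16.3- and 71.3-fold higher. Among the lowest, Gstp1, a glutathione transferase, was 13.3-fold lower, with 1.12 CPM in the PDGFRa and 177 CPM in the ligated tdTomato library. Plac9b was 12.6-fold, the glycolytic enzyme Eno1 7.40-fold and the cytokine Il6 7.24-fold lower. Adamts4, Dynlt1f, Igf2bp3, Ptn, H2-Q4, Grcc10, Hmgn2 and Mt2 were between 4.64- and 6.58-fold lower. Hic1 did not share that pattern, with 29.9 CPM in the PDGFRa and 32.2 CPM in the ligated tdTomato library, nor did Imp3, Il6, Adamts4 and Ptn, at 1.27, 0.815, 0.938 and 2.45 times in the PDGFRa over the ligated tdTomato library. Ly6a was 1.54, Pdgfra 1.41, Pi16 1.23, Col1a1 1.20 and Postn 1.12 times as high in citrine cells, while Runx1 (0.866, 0.676 to 1.13) and Acta2 (1.03, 0.933 to 1.15) showed no detectable difference. Rgs5 was 7.96-fold lower and tdTomato 354-fold lower. Eno1 and Rgs5 stood at 0.0872 and 0.0669 times in the PDGFRa over the ligated tdTomato library.

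The Sca1-high progenitor list had a median log2 ratio of 0.71 (percentile 99.9), with 4 of 12 members over 2-fold higher, among them Pcsk6 and Sema3c, and 0 lower. Resting cardiac fibroblast genes had a median of 0.50 (percentile 99.9), with 4 of 17 over 2-fold higher, such as Cxcl14 at 5.32-fold and C7 at 3.11-fold (C7 was also 6.50-fold higher in the PDGFRa than in the ligated tdTomato library). Basement membrane genes had a median of 0.65 (percentile 99.9), with Col4a1 2.57-fold and Lamc1 1.98-fold higher and 11 of 12 between. Matrifibrocyte and cartilage matrix genes stood lowest at -0.92 (percentile 0), with 6 of 13 over 2-fold lower, such as Col11a1 at 0.199 and Chad at 0.258 times. Adipogenic genes had a median of -0.68 (percentile 0.24; 2 of 12 higher, 3 lower), with Car3 at 0.0286 and Cd36 at 0.273 times against Cebpb at 43.9. Chemokines and cytokines had a median of -0.32 (percentile 2.14; 3 of 14 higher, 4 lower), with Ccl19 18.3-fold lower and Ccl2 2.33-fold higher; with no filter on cells (-0.31), at most 5% mitochondrial UMIs (-0.20) or resolution 0.5 (-0.32) they lay inside the random lists, as did adipogenic genes of at least 100 UMIs (-0.37). The other lists lay inside the central 95% of random lists, and their medians ran from -0.26 to 0.26. Several members named here and below followed the preparation pattern too: in the PDGFRa over the ligated tdTomato library Col4a1, Fbln2 and Timp2 were 2.72-, 2.55- and 2.55-fold higher, and Plau, Vegfa, Wnt11, Jund and Ctgf 8.39-, 12.2-, 12.3-, 14.4- and 25.6-fold. Among members lower in citrine cells, Pgk1, Cd36, Irf1 and Btg2 stood at 0.0196, 0.128, 0.575 and 0.630 times there. Col11a1, Spp1, Id1 and Rspo3 went the other way, at 5.21, 3.17, 1.90 and 1.64 times.

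Fibrillar collagens and elastic matrix had a median of 0.26 (percentile 97.0; 1 of 14 higher), with Fbln2, fibulin 2, at 3.00-fold. Crosslinking genes had a median of 0.26 (percentile 91.5; 1 of 14 higher), with Bmp1 at 2.31-fold. Growth factors and receptors had a median of 0.26 (percentile 91.9; 4 of 15 higher, 2 lower), with Igfbp7 16.1-fold and Vegfa 6.79-fold higher; Igfbp7 had 4816 CPM in the PDGFRa and 313 CPM in the ligated tdTomato library. TGF-beta and BMP signalling had a median of 0.04 (percentile 63.1; 3 of 16 higher, 4 lower), with Ctgf 14.0-fold higher and Id1 at 0.272 times. Complement genes had a median of 0.02 (percentile 64.0; 2 of 9 higher, 2 lower), with C4b 2.69-fold higher. Proteases and inhibitors had a median of 0.01 (percentile 61.3; 2 of 15 higher), with Plau 12.5-fold and Timp2 3.43-fold higher. ER folding genes had a median of -0.00 (percentile 66.0; 2 of 17 higher), with Xbp1 2.85-fold higher. Cell cycle genes (median -0.07, percentile 44.2; 1 of 22 higher, 1 lower) and Wnt modulators (median -0.07, percentile 29.8; 2 of 14 higher, 4 lower) held members on both sides, such as Wnt11 at 18.2-fold higher and Rspo3 at 0.127 times. Osteogenic genes had a median of -0.10 (percentile 23.8; 1 of 9 higher, 2 lower), with Spp1 at 0.392 times. Immediate early genes had a median of -0.18 (percentile 18.8; 5 of 17 higher, 2 lower), with Jund 10.9-fold higher and Btg2 at 0.279 times. Myofibroblast genes had a median of -0.19 (percentile 11.8; 1 of 16 higher, 4 lower). Interferon genes had a median of -0.26 (percentile 2.74; 1 of 16 higher, 2 lower), with Irf1 at 0.374 times, and glycolysis genes -0.26 (percentile 5.13; 1 of 13 higher, 3 lower), with Pgk1 at 0.165 times. In the citrine fibroblast-like cells the pericyte markers took 295, smooth muscle markers 234 and endothelial markers 169 CPM.

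Within the citrine hearts, Sca1-high-like cells carried more Fn1, Fbn1 and Cd34 RNA than the other fibroblast-like cells of the same heart, and much less Mgp and Apoe RNA. Fn1 rose by a log2 fold change of 2.17 (SE 0.068, adjusted p = 2.29e-18), from 75.5 ± 14.5 to 337 ± 59.2 CPM (SD, n = 3), and was higher in 3 of 3 hearts. Fbn1, the microfibril protein fibrillin 1, rose by 1.58 (adjusted p = 3.89e-18) and Cd34, a progenitor surface marker, by 0.94 (adjusted p = 1.93e-14). Mgp, matrix Gla protein, an inhibitor of calcification, fell by 3.71 (adjusted p = 1.86e-21), from 6949 ± 1249 to 528 ± 94.7 CPM, and Apoe, a lipid carrier, fell by 3.13 (adjusted p = 3.51e-18). The question was how the Sca1-high part of the Hic1+ cells differs from the rest. Only genes held out of the clustering entered the test. Of 238 such genes 179 passed, 49 up and 130 down, and 180 had an unadjusted p under 0.05. The 2 cell groups came from clustering these same cells, so held-out genes that vary with the clustering genes differ in part by construction. The p-values describe these clusters and do not test a grouping set beforehand. The hearts held 133, 169 and 236 Sca1-high-like cells and 1679, 2429 and 1839 others, which here included activated-like, interferon-like and cycling cells. The others also drew on a citrine cluster of 1512 cells with the Sca1-high genes Gfpt2, Ackr3, Cd55, Pcsk6 and Pi16 among its leading genes. It held 2 Sca1-high markers over 2-fold higher than in the rest of the library, against 9 in the Sca1-high-like cluster. The genes depended on how the Sca1-high-like cells were defined: with the libraries clustered together, a setting chosen after the data were seen, 195 genes passed, among them 160 of the 179 in the same direction, while 12 of the 179 turned.

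Matrix genes split between the cell groups. Of 11 fibrillar and elastic matrix genes tested, 3 rose and 6 fell, with Eln, elastin, down by a log2 of 1.70 and Bgn, biglycan, lower at -1.13. Of 13 crosslinking genes 4 rose and 6 fell; Bmp1, which cleaves procollagen, and Loxl2 rose by 1.40 and 1.00, and Lox fell by 2.56. Of 11 basement membrane genes 2 rose and 7 fell, Col15a1 at -1.55 and Col4a2 at -1.39. The activation genes were lower: 10 of 12 fell and 1 (Cnn2, 0.86) rose, with Ptn at -5.48, Meox1 at -2.45, Postn at -1.51 (adjusted p = 8.51e-08) and Runx1 at -0.95 (adjusted p = 0.00541). Another setting, chosen after the data were seen, left activated-like and interferon-like cells out of the others, while cycling cells stayed in. There 5 of 10 fell, Postn (-0.18, adjusted p = 0.443) and Runx1 (-0.66, adjusted p = 0.0573) did not pass, and Hic1 did (-0.15, adjusted p = 0.0271). Of 10 matrifibrocyte genes 8 fell and 0 rose, and in that setting 6 of 10 fell. Comp was at -5.33, Cilp at -2.90 and Thbs4 at -6.69 (SE 0.481), the last on 0.126 ± 0.219 CPM in Sca1-high-like cells, with none in 2 of the hearts. Of 14 resting cardiac fibroblast genes 2 rose, among them Scara5 (1.25), and 9 fell, among them Inmt at -4.04 and Hsd11b1 at -2.78. Wif1 had 0 counts in the Sca1-high-like cells of all 3 hearts, against 5.22 ± 3.97 CPM in the others. Hic1 itself did not pass the test (log2 fold change -0.12, SE 0.061, adjusted p = 0.0842), with 279 ± 5.93 CPM in Sca1-high-like and 304 ± 20.5 CPM in other cells.

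Signalling genes went both ways. All 14 growth factor and receptor genes passed, 4 up and 10 down, with Igfbp3 at -5.19, Gas6 at -1.72 and Igf1 at -1.66. Of 16 TGF-beta and BMP genes 2 rose and 10 fell, with Id1 at -2.35 and Ctgf at -1.34. Of 13 Wnt genes 2 rose, Wnt11 among them at 1.17, and 7 fell, such as Frzb and Dkk3, Wnt antagonists, at -2.51 and -1.99. Of 14 chemokine and cytokine genes 4 rose and 5 fell, with Tnfaip6, an anti-inflammatory hyaluronan-binding protein, at 1.78 and Cxcl12 at -1.56. Of 8 complement genes 5 fell, C4b at -2.50 and C1s1 at -1.44, and of 16 interferon genes 12 fell and 1 rose, with Ifit3 at -1.07. Without the activated-like and interferon-like cells, 9 of 15 interferon genes fell and 2 rose, and Isg15 went from -0.50 to -0.0040. Of 8 osteogenic genes 1 rose (Bmp2, 0.99) and 6 fell, Runx2 at -2.36, and of 6 adipogenic genes 1 rose (Zfp423, 1.09) and 4 fell, Lpl at -1.36. Of 14 proteases and inhibitors 4 rose and 4 fell, with Timp2 at 0.91 and Mmp3 at -3.88. Of 17 immediate early genes 3 rose and 11 fell, Klf4 at 0.78 and Jun at -0.71. Of 14 cell cycle genes 2 rose and 8 fell, Ccnb2 at -3.45. Of 13 glycolysis genes 5 rose and 2 fell, Hk2 at 1.01 and Gapdh at 0.67, and of 17 ER folding genes 8 rose and 2 fell. Adjusted over the list alone, 3 proteases fell, 4 glycolysis genes rose and 0 fell, and 7 ER folding genes rose, while the other lists had the same counts. Of the Sca1-high list 1 gene, Cd34, could be tested, since the rest had served to name or form the clusters.

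**Figure D3:**
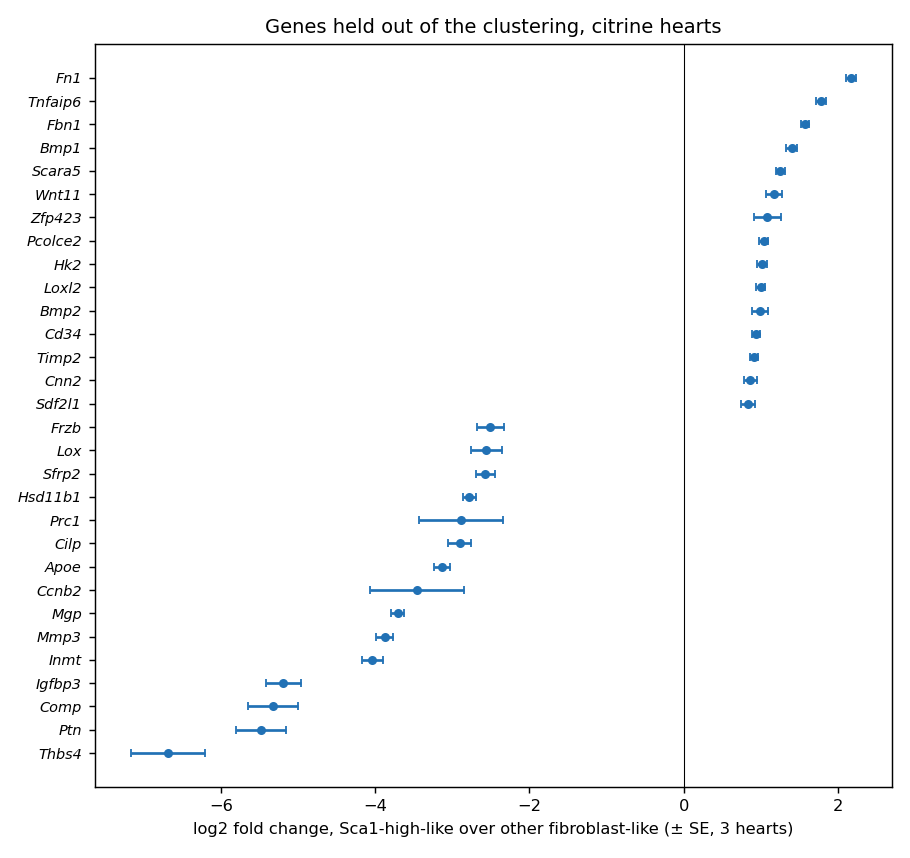
Log2 fold change (horizontal axis) in Sca1-high-like over other fibroblast-like cells of the 3 citrine hearts, with bars of 1 standard error, for the 15 highest and 15 lowest of the named genes with counts in both cell groups. Fn1 is highest at 2.17 and Thbs4 lowest at -6.69.

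The share of each class varied between the citrine hearts most for pericyte-like cells, which were 0.751%, 6.03% and 0.517% of the cells of the 3 hearts (mean 2.43% ± 3.12, SD, n = 3). Fibroblast-like cells were 95.8% ± 2.70, Sca1-high-like cells 8.09% ± 2.66, activated-like cells 6.19% ± 0.503 and interferon-like cells 1.86% ± 0.65. Cycling cells were 0.436% ± 0.480 and cells of the unnamed cluster 1.74% ± 0.427. Hic1 was at 302 ± 19.4 CPM and Pdgfra at 379 ± 20 CPM in fibroblast-like cells. A test of pericyte-like against fibroblast-like cells was not made, since 2 of the hearts held 14 and 11 pericyte-like cells, under the 30 set as the minimum.

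The 4 hearts of the PDGFRa library spanned wide ranges of activation and matrix genes. Postn was at 3317, 3872, 198 and 247 CPM in the fibroblast-like cells of the hearts with hashtags 1 to 4. Col1a1 was at 6811, 7508, 1157 and 1310 CPM, Cthrc1 at 795, 1141, 22.0 and 19.7 CPM, and Runx1 at 217, 223, 13.4 and 11.3 CPM. Tnc, Fn1, Lox and Ptn had medians of 157, 764.5, 208 and 1182 CPM over the hearts. The Sca1-high genes Ly6a and Pi16 ranged from 337 to 635 (median 481) and from 403 to 1008 (median 687) CPM. Pdgfra ranged from 98.2 to 207 (median 146) CPM and Hic1 from 23.1 to 38.7 (median 33.6) CPM. Activated-like cells were 13.2%, 11.5%, 0.0457% and 0.14% of the cells of these hearts, and Sca1-high-like cells 8.32%, 9.61%, 26.9% and 22.6%. The labels give 2 undamaged and 2 ligated hearts, but which hashtag marked which is not given in the sources used here, so ligated and undamaged PDGFRa hearts were not compared. The hearts held 3186, 3193, 2190 and 2146 assigned cells, with 34793363, 36671367, 14369249 and 14097154 UMIs for hashtags 1 to 4. Depth was thus higher in the hearts of hashtags 1 and 2, which also had more Postn and Col1a1 RNA.

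**Figure D4:**
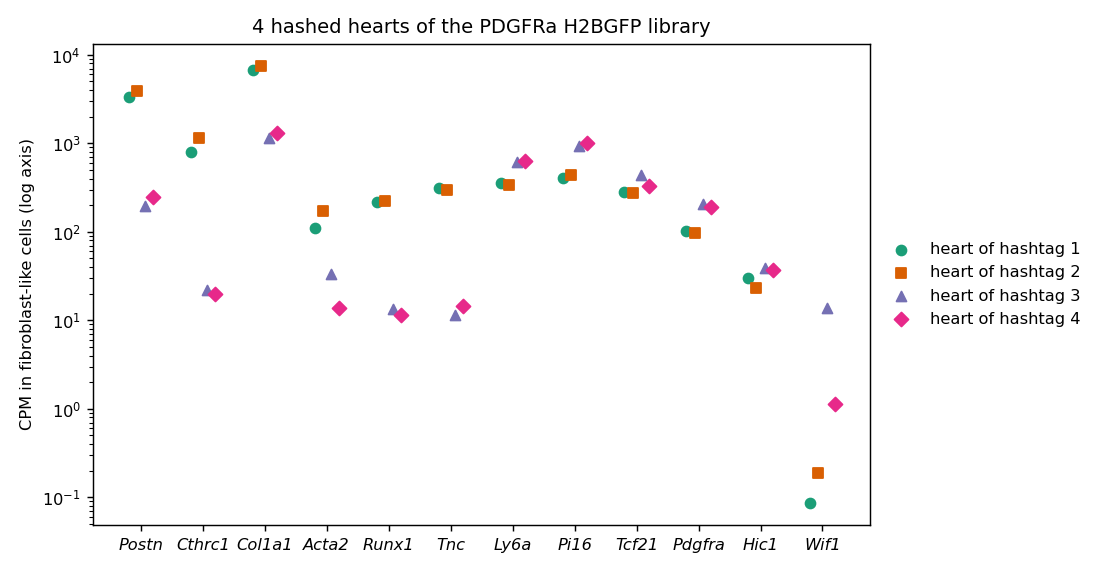
CPM (vertical log axis) of 12 genes in fibroblast-like cells of the 4 hashed PDGFRa hearts, with 1 point per heart and no condition assigned to any of them. Postn spans 198 to 3872 CPM and Hic1 23.1 to 38.7 CPM.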

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

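Of the tests in this part, the comparison of the PDGFRa with the ligated tdTomato library (for Hic1 and for the 135 genes) and the Hic1 ratio in pericyte-like cells were chosen only after the result was seen. Reporter and hashtag signals outside the comparisons came up where the labels name no source for them. The SSM2GFP sequence, which had 4066 UMIs in the PDGFRa library, had 7 UMIs in the undamaged tdTomato cells, 12 in the ligated ones and 217 in the citrine cells. The sources used here do not say whether it also matches citrine, so a source in the design of the citrine library is not excluded. Hashtag 4 had 2606 counts in the kept citrine cells, whose design names 3 hearts, with a highest count of 10 in a cell.

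The tdTomato sequence had 350 UMIs in 325 kept citrine cells, where the labels give no such transgene. A few cells that carry the transgene are argued against, since 0% of these UMIs lay in cells with 5 or more, while undamaged tdTomato cells held a mean of 4.64 each. A spread over all barcodes in proportion to their total UMIs is argued against as well: the highest count in a cell was 4, against 3 at the upper bound of 1000 redistributions, of which 2 reached 4, and 23 cells held 2 or more against an upper bound of 13, a second measure added after the first was seen. Of these UMIs 98.3% lay in fibroblast-like cells, which were 95.4% of the cells. An uneven spread of free RNA or misassigned reads may remain and was not tested, and no biological explanation was tested.

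Hic1 was 14.5-fold higher in citrine than in undamaged tdTomato fibroblast-like cells. A difference between the kinds of library preparation is argued against, since Hic1 in the PDGFRa library was 0.928 (0.843 to 1.02) times that of the ligated tdTomato library, whose preparations differ in the same way. The libraries of that pair also differ in mouse line, sorted cells and share of ligated hearts, so the preparation alone was not isolated. A transcript of the reporter allele that holds Hic1 sequence stays open: in pericyte-like cells Hic1 was also higher in the citrine library, 7.14-fold (4.67 to 11.5; 552 against 22 UMIs), which sorting on Hic1 would give too. Sorting on present Hic1 expression, the difference the design names, stays open as well: of Hic1-positive fibroblast-like cells at 2000 UMIs, 4.11% (2.14 to 7.07) held 2 or more Hic1 UMIs in the tdTomato libraries and 33.3% in the citrine library. By the bound written beforehand this explanation failed, since the tdTomato upper bound of 7.07% lay under the citrine lower bound of 31.9%. That bound was set aside, because it assumed that citrine-level cells are common among Hic1-positive tdTomato cells. Of all 5196 fibroblast-like tdTomato cells, 12 held 2 or more (0.231%, against 14.6% of citrine cells), which leaves room for at most 2.76% of citrine-level cells. A gate that took a small share may thus still give the difference. The share it took is not given in the sources used here.

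The 135 genes at least 4-fold higher in citrine than in undamaged tdTomato fibroblast-like cells may mainly reflect library preparation. Of them 91.1% were at least 2-fold higher in the PDGFRa than in the ligated tdTomato library, against an upper bound of 15.6% for random genes of like expression, and 75.8% of the 33 genes at least 4-fold lower went the same way; over 11859 genes, which are not independent replicates, the ratios had a Pearson r of 0.698 and a Spearman rho of 0.630. A shift common to genes of like GC content is argued against as the whole cause. The median log2 ratios of 20 GC bins ran from -0.0671 to 0.423, and 93.3% stayed at least 4-fold higher after these were taken off. Bin medians cannot show an effect on only some genes of a bin. The 135 genes had a median GC content of 54.5%, against 49.6% over 14167 genes, so a part for GC content stays open. Sorting on present Hic1 expression stays open: against the 176 undamaged tdTomato cells with a Hic1 UMI the median log2 ratio of these genes was 2.68, but against the cells without one it was 2.71, so choosing such cells moved nothing and the bound written for that test decides nothing. Hic1 itself was not higher in the PDGFRa than in the ligated tdTomato library. Mouse line differs together with preparation in both pairs, so the preparation alone was not isolated.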

How the results depend on the processing

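Leaving out the activated-like cluster or the cycling cells, and in the heart test leaving out activated-like and interferon-like cells, clustering the libraries together, using no filter on cells or at most 5% mitochondrial UMIs, were chosen only after the data were seen, as was leaving out cells with over 1 hashtag. With no replicate library and few cells in rare classes, depth limits shares near 0 and genes with few UMIs, and scrublet removed almost nothing from the citrine and PDGFRa libraries. Unless said otherwise, the cause of a change below was not tested.

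Of the alternative class shares 49 stayed within their interval and 23 did not. With no filter on cells, fibroblast-like shares were 92.3% (citrine) and 98.1% (PDGFRa), and Sca1-high-like shares 12.7% (undamaged tdTomato), 20.9% (citrine) and 18.1% (PDGFRa). At 5% mitochondrial UMIs, fibroblast-like shares were 89.6%, 77.3%, 96.7% and 99.49% in the undamaged tdTomato, ligated tdTomato, citrine and PDGFRa libraries, and Sca1-high-like shares 12.8%, 13.3%, 9.42% and 13.7%. Pericyte-like shares were then 5.71% (undamaged tdTomato) and 1.44% (citrine), and smooth-muscle-like shares 3.46% (undamaged) and 3.85% (ligated). Clustered together, Sca1-high-like shares were 0.179%, 0.0469%, 21.9% and 13.3% in the same order, and the citrine fibroblast-like share was 98.0%. At Leiden resolution 0.5 the undamaged tdTomato Sca1-high-like share was 9.73%. The means over the citrine hearts stayed within 1 SD. With 3 hearts, leaving out 1 cannot move a mean by 1 SD, so that bound decides nothing there. Leaving out 1 heart gave 95% to 97.4% for fibroblast-like, 0.634% to 3.39% for pericyte-like, 6.58% to 9.12% for Sca1-high-like, 5.90% to 6.36% for activated-like and 1.66% to 2.23% for interferon-like cells.

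Shares of cells with a UMI, given here for fibroblast-like cells, move with depth by construction. Thinned to 1000 UMIs, Hic1 shares were 2.16%, 3.44%, 26.2% and 3.36% in the undamaged tdTomato, ligated tdTomato, citrine and PDGFRa libraries, Pdgfra shares 24.2%, 19.4%, 30.03% and 14.3%, and the PDGFRa Mki67 share 0.119%. Unthinned, Hic1 shares were 7.30%, 13.4%, 83.4% and 22.9%, Pdgfra shares 58.9%, 56.0%, 85.2% and 62.4%, and Mki67 shares 0.510% (ligated), 0.435% (citrine) and 0.756% (PDGFRa).

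For ligated over undamaged lists, 244 alternative medians kept their direction and their side of the bounds. Over all kept cells, which adds pericyte-like and smooth-muscle-like cells by construction, basement membrane (-0.25) and resting fibroblast genes (-0.29) came to stand apart. Crosslinking (0.18), dissociation (0.16), matrifibrocyte (0.070) and glycolysis genes (-0.044) no longer did, and Igfbp5 (0.54) and Ly6a (-0.052) turned. At 100 UMIs, which leaves fewer genes, Wnt (-0.13) and matrifibrocyte genes (0.12) no longer stood apart, nor matrifibrocyte genes with no filter on counts (0.12) or glycolysis at 5% mitochondrial UMIs (-0.25). Without the activated-like cluster, which was named by such genes and left out of the ligated library only, fibrillar (-0.13), crosslinking (-0.014) and matrifibrocyte medians (-1.46) turned, the myofibroblast median (0.046) no longer stood apart and TGF-beta genes (-0.59) did. Col1a1 (-0.23), Col3a1 (-0.041), Ptn (-0.71), Sfrp2 (-0.37), Ifi44 (-0.53), Nrg1 (-0.24) and Acan (0) turned or reached 0. Without the cycling cells, which only the ligated library had as a cluster, the cell cycle median (-0.84), Cenpf (-0.85), Ccna2 (-1.55) and Ccnb2 (-0.51) turned. Of the single genes named, 171 more values moved, 170 in the same direction; the other was Mki67, from 0.54 to -1.25 without the cycling cells.

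For citrine over tdTomato lists, 230 alternative medians kept direction and side. Over all kept cells, fibrillar (0.34), glycolysis (-0.34), interferon (-0.45) and myofibroblast genes (-0.393) came to stand apart. Chemokines no longer did with no filter on cells (-0.31), at 5% mitochondrial UMIs (-0.20) or at resolution 0.5 (-0.32). At 100 UMIs adipogenic genes (-0.37) no longer did and interferon genes (-0.26) did, as they did with libraries clustered together (-0.42). Of 57 single gene values that moved, 56 kept their direction.

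In the heart test, every alternative count was within 1.5 times the 179 genes, but the genes were not all the same. DESeq2 gave 157, no TMM 178, no filter 187, hashtags at 80% of counts 167, resolution 0.5 181, and leaving out each heart between 164 and 171. Without the heart as a block, which ignores that both sums come from the same animal, 145 genes passed, 35 up and 110 down, all 145 among the 179. Clustering the libraries together gave 195 genes, of the 179 genes 160 in the same direction and 12 turned, and no filter on cells gave 191, with 150 in the same direction and 16 turned, Creld2 among them from 0.58 to -0.037. Mgp, from -3.71, came to -2.28 and -1.97 in these settings and Fn1, from 2.17, to 2.02 and 1.88, and Hic1 passed at -0.11 (adjusted p = 0.0172) and -0.15 (adjusted p = 0.00344). At most 5% mitochondrial UMIs gave 169. Against other cells without the activated-like and interferon-like ones, which keeps the cycling cells, 172 passed. Ltbp2 turned from -1.16 to 0.021 and Ifit1 from -0.47 to 0.17, and Ddah1, Scx and Racgap1 had too few counts to be tested. Leaving out activated-like cells lowers the activation genes of the others by construction: Postn (-0.18, adjusted p = 0.443) and Runx1 (-0.66, adjusted p = 0.0573) no longer passed, and Hic1 (-0.15, adjusted p = 0.0271) did. For the pericyte test and the PDGFRa test, the other tools, filters and hashtag rules and leaving out each heart were not run, since those tests were not made.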

Other observations

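The split test in this part was planned after its result was seen, and the pericyte and smooth muscle comparisons were chosen after the data were examined. After ligation, pericyte-like tdTomato cells carried more RNA of cytokine and matrix genes (816 cells with 2417571 UMIs against 186 undamaged cells with 312441). Il6, an inflammatory cytokine, was 11.2-fold higher (5.42 to 28.0), Ccl7 4.19-fold, and Cxcl10 had 153 UMIs against 0. Tnfaip6 was 4.58-fold and Mmp11, a matrix protease, 4.41-fold higher, and Timp1 15-fold (2.64 to 597) on 1 undamaged UMI. The fibrillar collagen list had a median log2 ratio of 0.90 (percentile 100; 5 of 14 over 2-fold higher), with Col1a1 at 2.12 times, and the cell cycle list one of 1.36 (percentile 100; 11 of 18), which came from the 7 cells of the cycling cluster: without them it was -0.28 (percentile 26.4) over 8 genes. Basement membrane, crosslinking, protease, myofibroblast and Sca1-high lists also stood above random lists, at 0.38, 0.42, 0.60, 0.56 and 0.90. Resting fibroblast (0.21, percentile 97.52) and chemokine genes (0.34, percentile 97.575) did so narrowly. Of 11 chemokine genes 5 were over 2-fold higher and 2 over 2-fold lower. Adipogenic genes stood below at -0.58. Endothelial markers, which share Cd36 and Fabp4 with the adipogenic list, summed to 1879 CPM in undamaged and 1244 CPM in ligated pericyte-like cells. Genes of fibroblasts went both ways, Htra3, Ly6a, Pi16 and Smoc2 at 4.41, 3.15, 2.58 and 2.46 times, Pdgfra at 1.13 (0.404 to 4.38), Tcf21 at 0.837 (0.526 to 1.40) and Abca8a at 0.558 (0.428 to 0.736) times, so RNA of fibroblasts in these cells is not excluded; the fibroblast markers summed to 6228 CPM in undamaged and 6786 CPM in ligated pericyte-like cells. Hic1 stood at 0.84 times (0.53 to 1.38) and Rgs5 at 0.98 times (0.95 to 1.01). One of the 2 pericyte-like clusters after ligation (330 cells) had Rgs16, Igfbp5 and Sele among its leading genes within the library. In smooth-muscle-like cells Fn1, Col1a1 and Postn were 4.92-, 3.56- and 3.52-fold higher after ligation, Acta2 was at 0.98 times (0.94 to 1.02) and Cxcl2 at 0.10 times. Clec3b, Cxcl14 and Htra3, genes of fibroblasts, were 6.35-, 4.82- and 2.42-fold higher. Pdgfra stood at 1.37 (0.26 to 13.5) and Tcf21 at 0.480 (0.263 to 0.884) times, and the fibroblast markers summed to 2818 and 3221 CPM. In fibroblast-like cells the same markers fell from 87467 to 48974 CPM. The near-level sums in pericyte-like and smooth-muscle-like cells thus leave room for a larger share of fibroblast RNA after ligation. Such RNA is not excluded as a source of the higher matrix genes in either class.

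For activation genes, the PDGFRa hearts of hashtags 1 and 2 lay apart from those of 3 and 4, a grouping made from these values. Depth parted the same way, with 34793363 and 36671367 UMIs for hashtags 1 and 2 and 14369249 and 14097154 for 3 and 4. Whether depth bears on the levels was not tested. Median log2 levels of the myofibroblast list against the mean of the 4 hearts were 1.02, 1.40, -1.01 and -1.51 for hashtags 1 to 4. They were 0.85, 1.10, -0.83 and -1.10 for matrifibrocyte genes, 0.54, 0.74, -0.67 and -0.62 for fibrillar collagens and 0.65, 0.36, -0.33 and -0.79 for chemokines. They were -0.52, -0.47, 0.57 and 0.45 for Sca1-high genes, -0.46, -0.55, 0.54 and 0.43 for resting fibroblast genes and -0.03, 0.09, 0.12 and -0.20 for dissociation genes. No condition was assigned to any hashtag from these values. Clusters of 1145, 1134 and 466 PDGFRa cells had Sfrp2, Ptn and Col1a1 among their leading genes without taking the activated name. A cluster of 66 cells had Saa3, Cxcl13, Clu and Wt1, an epicardial marker, among its leading genes.

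For the genes that differed between Sca1-high-like and other fibroblast-like cells of the citrine hearts, the 6 sums allow 10 splits into equal groups. The real split gave 179 genes and was the 1 split of 10 with as many; the highest other split gave 0. Only 4 of the 10 splits part the sums of every heart, as the pairing by heart asks, and the highest other one of these also gave 0. These splits are too few for a share under 0.05. In every other split each group also mixes sums of both cell classes. The difference between the classes then adds to the spread, so counts near 0 follow by construction. The contrast of 179 with 0 thus decides nothing.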
